A study of Homo sapiens with 4 samples.

How the data were processed

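Poly(A) RNA from cultured, untreated OS-RC-2 cells and cells derived from them was sequenced in 4 libraries. Per the labels' protocols, total RNA was isolated with RNeasy, poly(A) RNA was selected with Dynabeads and libraries were made with an Ion Total RNA-Seq kit, which is built for Ion Torrent sequencers. The authors deposited 1 table of RPKM values (reads scaled to the length of the gene model in kilobases and to the mapped reads of the library) with 57773 genes under Ensembl identifiers and 1 column per library. The submitters' processing notes name hg 19 as the genome build, and all coordinates here are on that build as the table gives them. The aligner, the read counter, their versions and the handling of reads with several matches are not given in the sources used here. Whether counting used the strand is likewise not given. Tested genes taken by the naming rule below that overlap another gene with at least 1 RPKM in any library are therefore named as such. Genes given outside that rule were not checked in this way.

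RPKM hides depth, but the deposited values fell on whole multiples of what 1 read is worth. The library totals were solved from 13 intronless mitochondrial genes, and each gene's read counts and model length were then solved from its 4 values. For 100% of the 11088 tested genes a length gave whole reads in all libraries, within 0.0002 reads or 2e-09 of the count where larger. The shortest such length was taken, so a true length may be a multiple of it. When the values of 1 library were scaled by 1.0137 in 2000 sampled genes, a length was still found for 1.7%. In 2000 simulated genes 97.2% came back exactly. The totals were 28278418 mapped reads for OSPa and 28876589, 26009797 and 29389632 for OS5K 1, 2 and 3. The median tested gene had 716, 690, 610 and 712 reads. Recovered reads were used for depth, for counting intervals on ratios (95%) and for 1 added alternative fit. A floor of 3 reads per library was used where a gene had 0 reads in OSPa. Intervals and floors cover counting error only.

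Groups follow the labels: OSPa (n = 1) and OS5K (n = 3). The test was limma (lmFit and eBayes with a mean-variance trend, two-sided) on log2(RPKM + 1) for genes with at least 1 RPKM in at least 1 library, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change on this scale understates the change of low genes, and its standard error (SE) comes from the same fit. The spread comes from the OS5K libraries alone (2 residual and 4.5 prior degrees of freedom), and the lone OSPa library is assumed to vary like them. The labels number the OS5K libraries without saying whether they are separate derivatives or cultures, so p-values measure only the spread between these samples, which may be technical. Ratios of mean RPKM are printed as folds. Counts of genes past a minimum fold, such as 2-fold, use the log2(RPKM + 1) scale instead.

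Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 22 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so it can hardly call a list here. A list that it does not call is not thereby shown to be unchanged. The 25 lists covered neutrophil-attracting CXC chemokines, NF-kB targets and cytokines, interferon-stimulated genes, MHC class I presentation, hypoxia-inducible factor targets, glycolysis, mesenchymal, epithelial and kidney tubule genes, matrix proteases, TGF-beta and YAP targets, cell cycle, cholesterol synthesis, oxidative phosphorylation, the unfolded protein and ATF4 response, NRF2 targets, immediate early genes, chromatin regulators, renal carcinoma drivers, leukocyte, endothelial and fibroblast markers, ribosomal proteins, histones and heat-shock genes. The test, the lists, the rule for named genes and all alternatives except the fit on recovered reads were chosen before the data were examined. The CXC chemokine and NF-kB lists were picked knowing that the study group has published on inflammation in these cells, so they are not independent evidence of direction.

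Genes were named by a fixed rule. It took the 15 largest rises and 10 largest falls by log2 fold change among genes past the threshold with all 3 OS5K libraries on 1 side of OSPa and a mean of at least 5 RPKM in a group. It added up to 4 members past the threshold from each list, or up to 2 members as values where none passed, and a short set chosen in advance (CXCL1, CXCL5, IL8, IL6, VHL, EPAS1, HIF1A, VEGFA, CDH1 and VIM among them). Some genes that the rule takes are not reported here. List members given outside the rule are CXCL3, IL1A, TNFAIP3, LCN2, CSF1, TRAF1, VCAM1, VLDLR, PTPRC, LYZ, CD3D and COL1A2. Other genes outside the rule whose values are given are said to be so where they appear.

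Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 RPKM, quantile normalization, TMM scaling, leaving out each OS5K library, limma without a trend or with robust moderation, a 2-fold minimum, and voom on the recovered reads, which was added after the data were seen. The fit was tested on simulated data: over 10 simulations of 11088 genes with 200 changed, 88.2% of genes changed 2-fold and 100% of those changed 4-fold were recovered, and 10% of calls were false. A list of 20 genes shifted by 0.5 log2 was called in 10 of 10 simulations, and 1 of 230 unchanged lists was called. GC content and gene type came from GENCODE 29 by Ensembl identifier. GC content and model length were at hand for 98.3% of tested genes. R 4.3.3, limma 3.58.1 and Python 3.11.15 were used.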

Results

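RNA was measured in OS-RC-2, a human clear cell renal cell carcinoma line grown in serum-containing medium, and in cells derived from it. One library was named OSPa and 3 were named OS5K and numbered 1 to 3. The labels spell out neither name and do not say how the derivatives were made. The libraries held between 26009797 and 29389632 mapped reads, of which 89.3% to 90.3% lay in genes. Mitochondrial genes took 3.0% to 3.8% of reads, and 10285 to 10458 genes reached 1 RPKM in each library.

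The comparison asked which genes differ between the OS5K derivatives and OSPa. IGFBP5, a secreted binding protein of insulin-like growth factors, went from 0.736 RPKM in OSPa to 203 ± 7.80 (SD, n = 3) in OS5K, a ratio of 276 (counting interval 233 to 330). CCL20, a chemokine for lymphocytes and dendritic cells, went from 0.530 to 53.4 ± 8.54 RPKM, and GJB2, which encodes the gap junction protein connexin 26, from 11.3 to 296 ± 73.0 RPKM. UQCRH, a subunit of mitochondrial complex III, fell from 54.1 to 0.823 ± 0.142 RPKM. TENM2, a teneurin cell adhesion protein, fell from 40.6 to 2.36 ± 0.255 RPKM.

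In all, 731 of 11088 genes (6.6%) passed the limma threshold, 356 higher and 375 lower in OS5K, and 652 of them were protein-coding. TMM scaling gave 388 higher and 272 lower, so the balance of directions depends on scaling. The median log2 change of all tested genes was -0.071, and camera sets each list against the other tested genes rather than against 0. On the log2(RPKM + 1) scale a change of at least 2-fold was seen for 360 of the 731, 205 higher and 155 lower. That scale leaves out called low genes with larger RPKM ratios, such as OAS2 (5.38-fold lower, -0.82 log2) and MME (2.75-fold higher, 0.84 log2). All 731 had their 3 OS5K values on 1 side of OSPa, which the call all but requires, since its spread comes from the OS5K libraries. Of all tested genes 65.5% had them on 1 side, against 50% if the 4 values had no order. Each OS5K library differed from OSPa by 2-fold or more on the log2(RPKM + 1) scale at 424, 448 and 492 genes, and from another OS5K library at 34 to 53 genes. In 282 genes all 3 OS5K libraries lay at least 2-fold from OSPa in the same direction, 165 higher and 117 lower. With pseudocounts of 0.1 and 5 this became 548 and 91 genes. Without the filter on low values 650 genes passed, of which 154 were among the 731, and 44 of the 72 named genes past the threshold, such as CXCL5, VEGFA and HIF1A, lost their call.

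**Figure D1:**
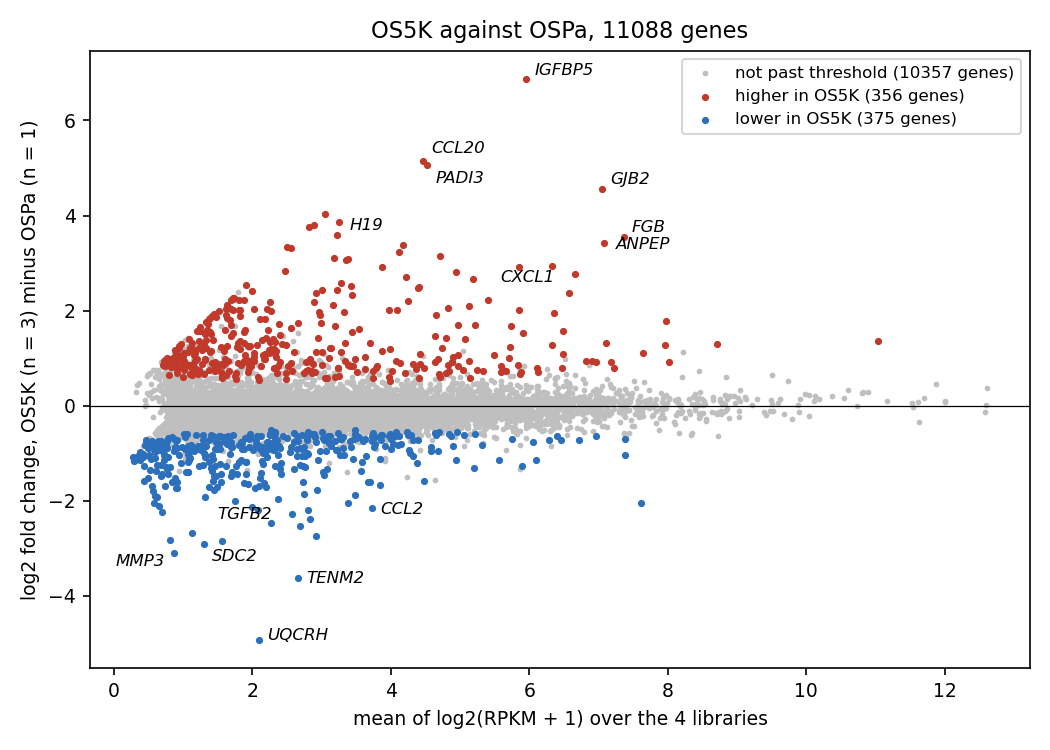
Log2 fold change of OS5K (n = 3) over OSPa (n = 1) on the log2(RPKM + 1) scale against the mean level over the 4 libraries, 1 point per tested gene, with the 356 genes past the limma threshold on the higher side in red and the 375 on the lower side in blue. IGFBP5 is the highest point and UQCRH the lowest.

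Among the largest rises, IGFBP5 (chromosome 2, 217536828 to 217560248) changed by 6.88 ± 0.12 log2 (SE, limma adjusted p = 7.922e-06), CCL20 by 5.14 ± 0.19 (limma adjusted p = 0.0001101) and GJB2 by 4.57 ± 0.26 (limma adjusted p = 0.0005736). PADI3, a peptidylarginine deiminase, rose from 0.654 to 55.8 ± 15.2 RPKM. GJB6, the connexin 30 gene next to GJB2 on chromosome 13, had 1 read in OSPa and 17.8 ± 11.6 RPKM in OS5K, a ratio of 1128 with a counting interval of 204 to 44980. Without OS5K 1 its mean was 11.1 RPKM and the ratio 702. The imprinted noncoding RNA H19 rose from 0.277 to 17.8 ± 2.72 RPKM, and FAM83A from 5 reads to 13.6 ± 4.02 RPKM. NPPC, which encodes C-type natriuretic peptide, had 0 reads in OSPa and 12.5 ± 0.499 RPKM in OS5K. The OS5K mean was 126.7 times the 3-read floor in OSPa, and the lower counting limit of the ratio was 102.9. AC006372.6 also had 0 reads in OSPa. Its OS5K mean of 9.93 ± 5.13 RPKM, with 4.74 in OS5K 1, was 13.66 times its 3-read floor, with a lower counting limit of 10.75. PNCK, FGB (the fibrinogen beta chain), PAGE5, CASP14 and S100A4 completed this set, with FGB going from 24.9 to 304 ± 9.95 RPKM and S100A4 from 2.24 to 30.1 ± 8.41 RPKM. ANPEP, the aminopeptidase N gene of proximal tubule brush border, rose from 21.7 to 246 ± 44.2 RPKM. PNCK overlaps SLC6A8, S100A4 overlaps S100A3 and IGFBP5 overlaps AC007563.5. The calls of GJB6 and AC006372.6 were lost in the voom fit (limma adjusted p = 0.167 and 0.075), and that of CASP14 too (limma adjusted p = 0.146). AC006372.6 and CASP14 also lost theirs with a pseudocount of 5 (limma adjusted p = 0.0558 and 0.0811) and with robust moderation (0.0565 and 0.0708). CASP14 had 4 reads in OSPa and a mean of 10.7 RPKM in OS5K, or 6.71 RPKM without OS5K 3.

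UQCRH (chromosome 1, 46769303 to 46782448) fell by 4.92 ± 0.13 log2 (SE, limma adjusted p = 5.459e-05), from 2156 reads in OSPa to 29, 36 and 32 reads. TENM2 fell by 3.63 ± 0.13 (limma adjusted p = 0.0001101). MMP3, the stromelysin 1 gene, had 472 reads in OSPa and 5, 2 and 4 in OS5K, and fell by 3.11 ± 0.13 log2. SOCS2, a suppressor of cytokine signalling, fell from 6.58 to 0.0775 ± 0.0123 RPKM and overlaps SOCS2-AS1. SDC2, a cell-surface proteoglycan, fell from 10.2 to 0.485 ± 0.119 RPKM, and APBB1IP, an adaptor of integrin activation, from 12 to 0.801 ± 0.0378. CCDC80, ANKRD1, EDN2 (endothelin 2) and GFRA1 (a co-receptor of the neurotrophic factor GDNF) made up the rest, with log2 changes of -2.73, -2.67, -2.53 and -2.47.

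**Figure D2:**
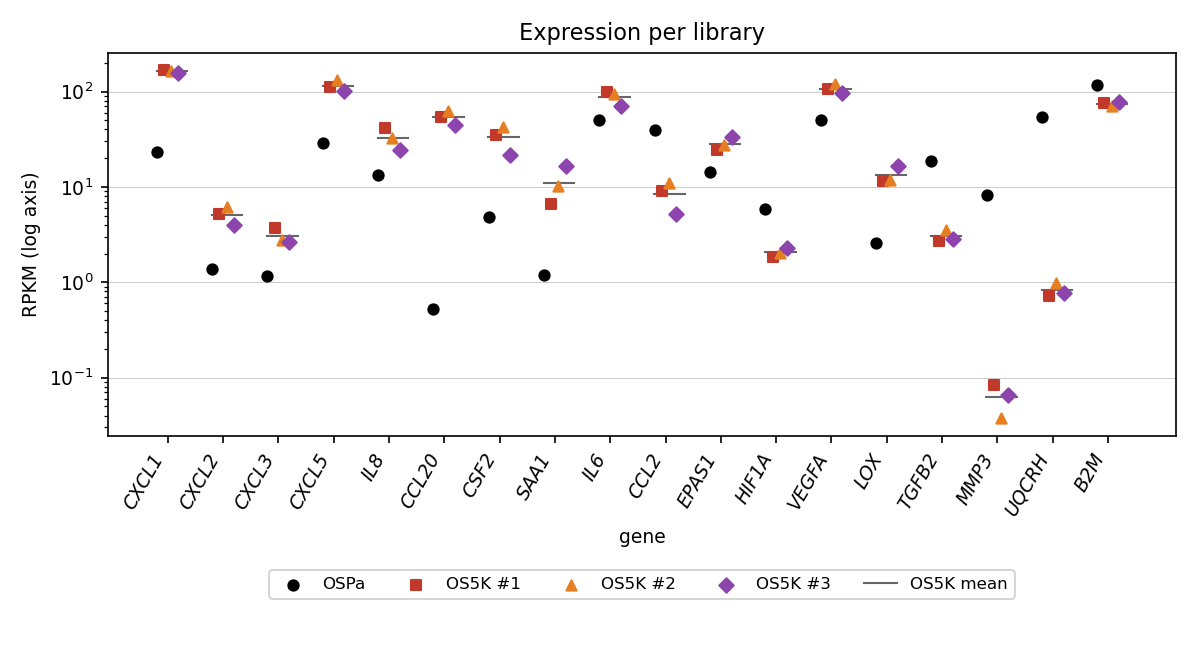
RPKM of named genes, and of CXCL3 from outside the naming rule, in each library on a log axis, with OSPa and the 3 OS5K libraries as separate points. Grey lines mark the OS5K mean (n = 3). For every gene drawn the 3 OS5K points lie on 1 side of the OSPa point, and IL6 alone of these genes missed the limma threshold.

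All 5 tested neutrophil-attracting CXC chemokines rose. This list and the NF-kB list were chosen with earlier work on these cells in mind and are not independent evidence of direction. CXCL1 (chromosome 4, 74735110 to 74736959) went from 22.9 to 163 ± 6.25 RPKM (7.09-fold, limma adjusted p = 0.0002356), and CXCL5 from 28.6 to 114 ± 15.2 RPKM (log2 change 1.95, limma adjusted p = 0.002112). CXCL2 went from 1.39 to 5.11 ± 1.11 RPKM, CXCL3 from 1.16 to 3.05 ± 0.550 and IL8 from 13.2 to 32.9 ± 8.75. The count was also 5 higher and 0 lower adjusted over the list alone, with a median log2 change of 1.34 (camera adjusted p = 5.53e-08). The adjusted p was 0.443 with an estimated correlation, and 0.0474 by fry. That estimate was 0.642, against the preset 0.01. IL8, CXCL1, CXCL5 and CXCL2 lie close together on chromosome 4, between 74606223 and 74965010, so their rises need not be independent. IL8 sat at the threshold (limma adjusted p = 0.04976) and lost its call without OS5K 2 (limma adjusted p = 0.0754), with a pseudocount of 5 (0.0578), without a trend (0.0518), with robust moderation (0.0627) and without the filter on low values (0.264). CXCL6 and PPBP were too low to test.

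NF-kB targets and cytokines went both ways. Of 27 tested, 6 rose and 4 fell, or 11 and 4 adjusted over the list alone. CSF2, the growth factor GM-CSF, rose from 4.79 to 32.9 ± 10.6 RPKM, and SAA1, an acute-phase protein, from 1.2 to 11.1 ± 5.02. CCL2, a monocyte chemokine, fell from 39.1 to 8.44 ± 2.94 RPKM and overlaps AC005549.3. IL1A, CCL20, TNFAIP3 and LCN2 were also higher, and CSF1, TRAF1 and VCAM1 also lower. IL6 had 50.1 RPKM in OSPa and 87.1 ± 15 in OS5K and missed the threshold (limma adjusted p = 0.08492), but passed without OS5K 3 (limma adjusted p = 0.0228) and with voom (0.0402). The median log2 change of the list was 0.23 (camera adjusted p = 0.000726). The adjusted p was 0.599 with an estimated correlation and 0.192 by fry. The SAA1 call was lost in the voom fit (limma adjusted p = 0.0779), with a pseudocount of 5 (0.054) and with robust moderation (0.0626).

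Of 13 MHC class I presentation genes tested, 3 fell and 10 did not pass. HLA-B, which presents peptides to T cells, fell from 41.1 to 20.8 ± 1.34 RPKM, the peptide transporter TAP1, which overlaps PSMB9, from 15.3 to 7.04 ± 0.773, and B2M, the light chain of class I molecules, from 116 to 74.6 ± 4.53. Adjusted over the list alone, 0 rose and 6 fell, with a median log2 change of -0.35 (camera adjusted p = 0.0131), or -0.20 with a pseudocount of 5. The adjusted p was 0.443 with an estimated correlation. B2M lies on chromosome 15, whose genes had a median below that of all genes, and lost its call without OS5K 1, 2 or 3 (limma adjusted p = 0.0849, 0.0675 and 0.0673) and under TMM scaling and quantile normalization (limma adjusted p = 0.0703 and 0.0558). Of 18 interferon-stimulated genes tested, 1 rose (OASL, 2.29 to 5.19 ± 0.416 RPKM) and 2 fell (OAS2 and XAF1), with the same counts adjusted over the list alone (camera adjusted p = 0.145). OAS2 lost its call without OS5K 1 or 2 (limma adjusted p = 0.0580 and 0.0649), and XAF1 without OS5K 2 or 3 (limma adjusted p = 0.0610 and 0.0641). XAF1 also lost it under quantile normalization and TMM scaling (limma adjusted p = 0.0587 and 0.0516), and OAS2 with a pseudocount of 0.1 (0.101).

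Targets of hypoxia-inducible factor, the pathway switched on by VHL loss in clear cell carcinoma, rose in part. VEGFA went from 49.7 to 107 ± 12.7 RPKM (2.16-fold, limma adjusted p = 0.01354), LOX, a collagen cross-linking enzyme, from 2.59 to 13.3 ± 2.71, NDRG1 from 14.3 to 49.9 ± 11.6 and ANGPTL4 from 38.8 to 120 ± 33.4. Of 22 tested, 7 rose and 1 (VLDLR) fell, or 8 and 3 adjusted over the list alone. CA9 (54.9 to 20.2 ± 12.5 RPKM) and STC2 (14.3 to 7.81 ± 1.58), outside the naming rule and chosen after their values were seen, had lower means but did not pass (limma adjusted p = 0.1454 and 0.06548). CA9 had 34.6, 14.2 and 11.8 RPKM in OS5K 1, 2 and 3. The median log2 change was 0.07, from 0.003 without the filter on low values to 0.219 with a filter at 5 RPKM and 0.117 without OS5K 3, and the camera adjusted p was 0.00762, against an adjusted p of 0.443 with an estimated correlation and 0.0825 by fry, and the list's call was lost without the filter on low values (camera adjusted p = 0.0667). ANGPTL4 lost its call without OS5K 1 (limma adjusted p = 0.0630), and LOX overlaps SRFBP1. Of 19 glycolysis genes none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.305). The furthest from 0 were ALDOC at -0.54 and ENO2, which overlaps LRRC23, at 0.37.

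Genes for 2 alpha subunits of hypoxia-inducible factor changed, in opposite directions. HIF1A fell from 5.89 to 2.05 ± 0.223 RPKM (limma adjusted p = 0.005395) and overlaps HIF1A-AS1. EPAS1, which encodes HIF-2 alpha, rose from 14.5 to 28.4 ± 4.41 RPKM (limma adjusted p = 0.0347), a call lost without OS5K 2 (limma adjusted p = 0.0511). VHL itself had 2.91 RPKM in OSPa and 2.50 ± 0.210 in OS5K (limma adjusted p = 0.5459). Of 15 renal carcinoma drivers tested, 1 rose (EPAS1) and 1 fell (HIF1A), with the same counts adjusted over the list alone (camera adjusted p = 0.316).

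Mesenchymal and epithelial genes each held members that rose and members that fell. Among 18 mesenchymal genes, 2 rose and 5 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.916). The gelatinase gene MMP2 rose from 12.2 to 34.7 ± 5.56 RPKM and COL1A1 from 5.88 to 11.3, while the matrix protein POSTN fell from 1.61 to 0.0823 ± 0.0433, the transcription factor SNAI2 from 20.6 to 9.40 ± 1.21, and TAGLN and ACTA2 by 1.04 and 0.93 log2. VIM, the vimentin gene, which overlaps VIM-AS1 and RP11-124N14.3, had 1558 and 1883 ± 185 RPKM (limma adjusted p = 0.4673). Among 12 epithelial genes, 3 rose and 3 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.726). The claudins CLDN4 (26.3 to 78.1 ± 11.6 RPKM) and CLDN1 (7.50 to 18.8) and the junction gene JUP rose, and KRT8, which overlaps KRT18, fell from 283 to 138 ± 10.4 RPKM. CDH1 stayed under 1 RPKM in every library and was not tested, at 0.994 in OSPa and 0.40, 0.42 and 0.58 in OS5K. The COL1A1 call was lost without OS5K 1 (limma adjusted p = 0.0719), TAGLN overlaps PCSK7, ACTA2 overlaps FAS and STAMBPL1, and JUP overlaps EIF1. The mesenchymal median was -0.03, above the -0.071 of all tested genes, and camera leaned up. The epithelial median was -0.25 against a mean of 0.06.

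Kidney tubule genes included 3 that rose and 1 that fell of 10 tested, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.0509). The list's median was 0.09, and it passed with a pseudocount of 0.1 (median 0.17, camera adjusted p = 0.0492) and with voom (0.18, 0.0326), while the median was -0.04 with a filter at 5 RPKM. PAX8, a renal lineage factor, rose from 24.8 to 53.2 ± 2.53 RPKM while its relative PAX2 fell from 8.71 to 3.07 ± 0.619. MME (neprilysin) rose from 0.828 to 2.28 RPKM. Matrix proteases and their inhibitors split, with 4 higher and 3 lower of 13, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.316). The collagenase MMP1 rose from 1.56 to 7.85 ± 3.19 RPKM, while MMP13, another collagenase, fell from 2.73 to 0.0803 and the inhibitor TIMP2 from 5.82 to 1.0. The protease list had a median of 0.22 and a mean of -0.04, and passed with a filter at 5 RPKM (median 0.43, camera adjusted p = 0.00208). MMP1 lost its call without OS5K 1 (limma adjusted p = 0.0506), with a pseudocount of 5 (0.0699) and with robust moderation (0.0666). Of 17 TGF-beta and YAP targets, 1 rose (ID2) and 3 fell (TGFB2, ANKRD1 and ID3), or 2 and 6 adjusted over the list alone (camera adjusted p = 0.257, fry 0.0474). The ligand gene TGFB2 fell from 18.6 to 3.03 ± 0.438 RPKM (limma adjusted p = 0.0008013). ID2 lost its call without OS5K 1 or 3 (limma adjusted p = 0.0970 and 0.0800) or without a trend (0.0503), and ID3 without OS5K 3 (limma adjusted p = 0.0541).

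**Figure D3:**
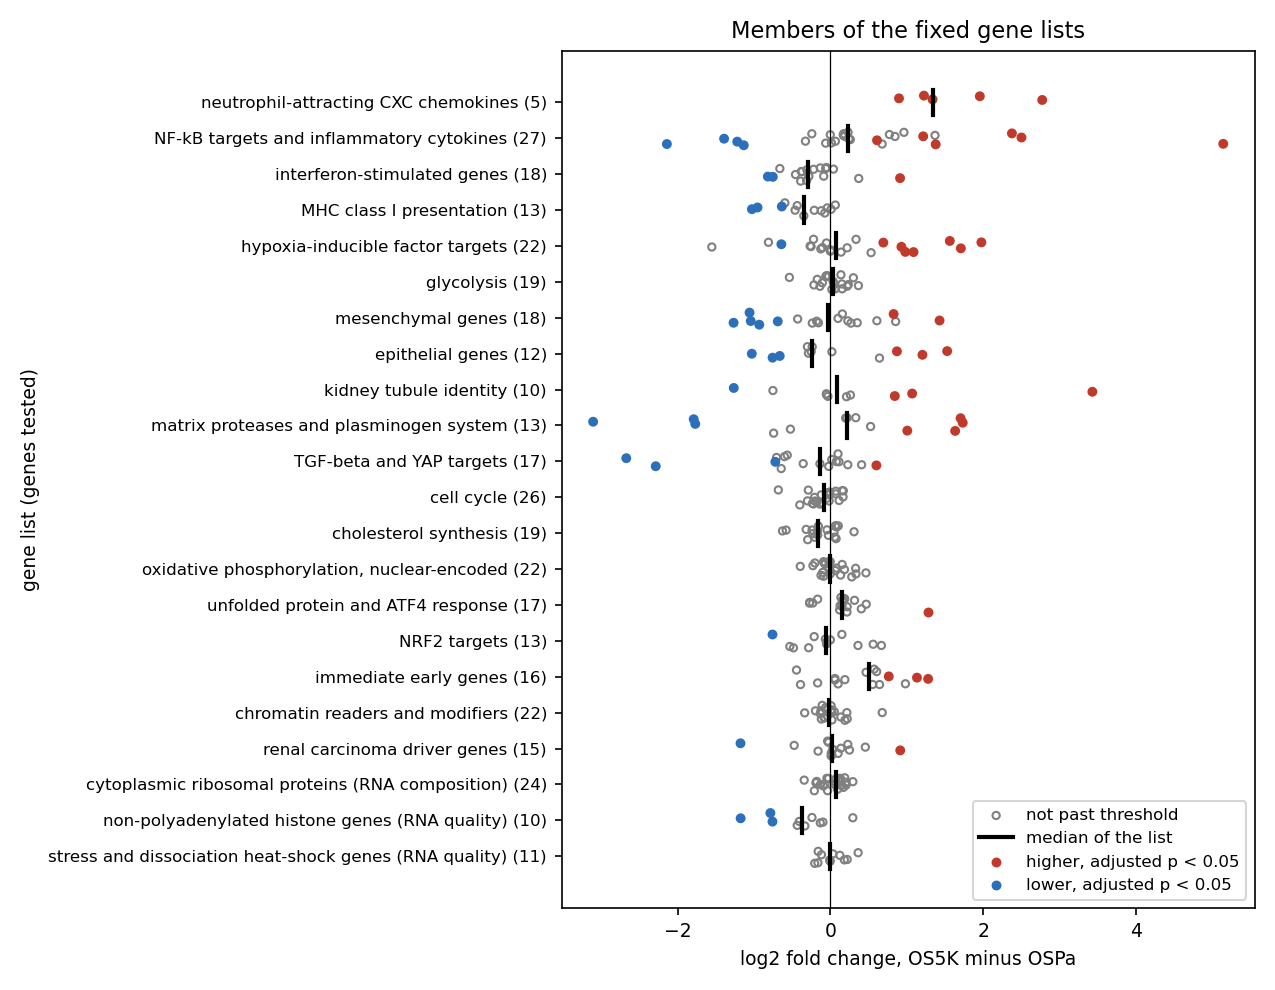
Log2 fold change of OS5K (n = 3) over OSPa (n = 1) for the tested members of the gene lists, 1 point per gene, grouped by list, with genes past the limma threshold in red (higher) or blue (lower) and a black bar at each list's median. All 5 tested CXC chemokines are past the threshold above 0, against 6 above and 4 below of 27 NF-kB targets.

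Immediate early genes, the first to respond to growth signals, leaned up. Of 16 tested, 3 rose and 0 fell, or 8 and 2 adjusted over the list alone, with a median log2 change of 0.51 (camera adjusted p = 0.000101), or 0.18 with a pseudocount of 5 and 0.19 without the filter on low values. The adjusted p was 0.443 with an estimated correlation and 0.0474 by fry. KLF4 rose from 0.270 to 2.10 RPKM, the phosphatase gene DUSP5 from 3.20 to 8.23, and KLF6 from 12.8 to 22.4, the last lost without OS5K 1 or 3 (limma adjusted p = 0.0606 and 0.0554). In the unfolded protein and ATF4 list, 1 of 17 rose, or 2 adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.00762), or 0.24 under TMM scaling. The adjusted p was 0.443 with an estimated correlation. DDIT4, an inhibitor of mTOR signalling that overlaps RP11-442H21.2, rose from 127 to 311 ± 47.2 RPKM.

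Several further lists held no gene past the threshold over all genes tested. The oxidative phosphorylation list is partial and leaves out UQCRH, which fell past the threshold (limma adjusted p = 5.459e-05). These were cell cycle (26 tested, camera adjusted p = 0.691), cholesterol synthesis (19, 0.49), oxidative phosphorylation (22, 0.265), chromatin regulators (22, 0.39), ribosomal proteins (24, 0.193) and heat-shock genes (11, 0.39). Adjusted over the list alone, cholesterol synthesis had 0 higher and 2 lower and the other lists had 0. Members further from 0 than most included PCNA at -0.68, E2F1 at -0.40, DHCR7 at -0.58, COX6C at 0.46, COX5A at -0.40, DNMT3B at 0.68, EED at -0.34, RPL4 (overlapping ZWILCH) at -0.34, RPL30 (overlapping MATN2) at 0.29, DNAJB1 (overlapping TECR) at 0.36 and HSPA1B at 0.22 log2. COX5A and RPL4 lie on chromosome 15, PCNA, E2F1 and DNMT3B on chromosome 20, and DHCR7 and EED on chromosome 11, whose genes had medians below that of all genes. PCNA (limma adjusted p = 0.05054) and DNMT3B (0.05082) missed the threshold narrowly. PCNA passed under 6 of the 12 alternative settings, among them quantile normalization (limma adjusted p = 0.0343) and voom (0.0222). DNMT3B also passed under 6, among them TMM scaling (limma adjusted p = 0.0377) and leaving out OS5K 2 (0.0486). Of 13 NRF2 targets AKR1B10 alone fell, from 6.51 to 3.41 RPKM, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.963).

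Most markers of other cell types were too low to test, with CD68, CD3D, COL1A1 and ACTA2 as the exceptions. PTPRC, the pan-leukocyte gene, had 0 reads in OSPa and 1, 0 and 0 in OS5K, and LYZ had at most 1 read. Of 19 leukocyte markers 2 could be tested, and CD68, a lysosomal protein gene that overlaps AC113189.5 and SNORA67_8, rose from 30.0 to 55.0 ± 6.48 RPKM, a call lost without OS5K 3 (limma adjusted p = 0.0541). Adjusted over the list alone 2 were higher, the other being CD3D at 6 reads in OSPa and 14, 26 and 30 in OS5K. None of 12 endothelial markers reached the filter. Of 13 fibroblast markers COL1A1 rose and ACTA2 fell, with the same counts adjusted over the list alone. COL1A2, outside the naming rule and under the filter, had 3 reads in OSPa and 175, 237 and 275 in OS5K. Of 10 histone genes tested, 3 fell, or 4 adjusted over the list alone (camera adjusted p = 0.0356, and adjusted p = 0.72 with an estimated correlation). HIST1H2BK fell from 21.1 to 8.87 RPKM, and HIST1H2AC and HIST1H2BD by 0.79 and 0.76 log2, the last call lost with voom (limma adjusted p = 0.0583). The list was fixed for histone genes without poly(A) tails, but these 3 are known to make polyadenylated transcripts as well. That list lost its call without OS5K 1 (camera adjusted p = 0.0996) or OS5K 3 (0.0914), without the filter on low values (0.231), in the voom fit (0.113) and by fry (0.192).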

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

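The fit on recovered reads was chosen after the data were seen, and the other settings before. Against 731 genes (356 higher, 375 lower), quantile normalization gave 613, TMM scaling 660, pseudocounts of 0.1 and 5 gave 723 and 745, robust moderation 809, limma without a trend 721 and voom on recovered reads 946. Leaving out 1 OS5K library gave 634 to 659. A filter at 5 RPKM left fewer genes to test and gave 484 genes, 229 of them higher, and a 2-fold minimum gave 360 (205 higher and 155 lower). Without a filter 650 genes passed, but only 154 were among the 731, with 67 higher and 583 lower, and the cause was not tested. The count of genes with all OS5K libraries at least 2-fold from OSPa moved from 282 to 548 and 91 with pseudocounts of 0.1 and 5, which weight low genes differently, and to 708 and 55 with minimum folds of 1.5 and 4. The 7 gene lists past the threshold became 0 with an estimated correlation, and 5 to 8 in the other settings. With it, unadjusted camera p went from 9.14e-06 to 0.0414 for immediate early genes. It went from 0.00357 to 0.091 for MHC class I and from 0.00173 to 0.0777 for ATF4 genes. Their estimated correlations (-0.024, -0.066 and -0.007) were under the preset 0.01, so a raised correlation does not explain their loss. The other lists past the threshold had estimates above it (0.022 to 0.72).

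Of the 72 named genes past the threshold, 0 changed sign in any setting, 44 lost the call without a filter, 17 in at least 1 other setting and 12 without 1 OS5K library. Of 16 that had not passed, 4 did so in some setting. The camera direction of some lists that had not passed turned, and the cause was not tested: the epithelial list without a filter (median -0.033), the mesenchymal list under quantile normalization (-0.067) and TMM scaling (0.045), and NRF2 targets with voom (-0.054) and without OS5K 2 (-0.054) or OS5K 3 (-0.047), though not without OS5K 1 (-0.083). By fry the mesenchymal (-0.03), epithelial (-0.246), protease (0.218) and renal driver (0.018) lists leaned the other way. Fry sets a list against 0, where camera sets it against the other tested genes, so the directions can differ. No paired analysis was possible because OSPa has a single library. Genes with few reads, such as GJB6 with 1 read in OSPa, have folds that depth limits.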

Other observations

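The genes in these first paragraphs lie outside the naming rule and were chosen after their values were seen, and the tests of the splits and of chromosome 15 dosage were chosen after the result was seen. All 3 fibrinogen chain genes rose together on chromosome 4. FGA went from 0.161 to 4.49 ± 1.07 RPKM (SD, n = 3; limma adjusted p = 0.003227) and FGG from 1.09 to 17.2 ± 4.06 (limma adjusted p = 0.001661), beside FGB. Single genes that rose included the GTPase gene RAC2, from 19.2 to 81.3 ± 10.1 RPKM, PLEK from 0.128 to 5.06 ± 0.630, SRGN from 4.49 to 21.5 ± 4.38, and the chemokine receptor CXCR4 from 1 read to 3.83 ± 0.943 RPKM. The actin-bundling gene LCP1 fell from 37.7 to 15.9 ± 2.16 RPKM.

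NDUFA4L2 (26.9 to 143 ± 5.69 RPKM, limma adjusted p = 0.0004969), STC1 (2.21 to 9.89 ± 2.65) and the lipid droplet gene PLIN2 (10.7 to 31.5 ± 5.92) also rose. The adhesion gene L1CAM rose from 6.15 to 50.2 ± 13.2 RPKM and the creatine transporter SLC6A8, which overlaps PNCK, from 16.5 to 133 ± 4.91. Genes that fell included THBS1 (567 to 138 ± 26.0 RPKM, on chromosome 15), COL5A2 (29.2 to 6.29 ± 0.606) and the neighbouring basement membrane genes COL4A5 (6.25 to 1.67 ± 0.145) and COL4A6 (2.46 to 0.242 ± 0.0835), while COL1A1 rose.

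The count of 731 genes was set against each OS5K library standing alone in turn. Those 3 splits called 0 genes by limma, with 108, 347 and 187 genes at an unadjusted p under 0.05, so 1 of 4 splits gave as many genes. In each of them OSPa was among the 3 libraries set against the lone one, so its difference widened the spread. Their 0 calls therefore do not show how alike the OS5K libraries are. With 4 splits the share cannot fall under 0.05. After each library's trends on GC content and gene length were removed, 90.8% of the called genes with both values kept their call, which argues against such a trend as the whole cause. A difference in culture or library preparation between OSPa and OS5K cannot be told apart from the groups, since OSPa has 1 library, and the difference the labels name, derived cells, stays open and untested.

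The fall of UQCRH was large in all 3 OS5K libraries. Whether reads moved to its near-identical copy UQCRHL stays open. UQCRHL and the other copies in the table, 5 in all, were listed at 0 in every library, OSPa included, so 0.0% of the lost reads was gained there. The bound set in advance for that gain decides nothing, since no gain could appear if the counting dropped reads that match several copies, which the sources used here do not tell. Loss of a large segment of chromosome 1 was argued against by the 33 tested genes within 2 Mb, whose median log2 change was 0.027 (quartiles -0.135 and 0.154). No biological explanation was tested.

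Neighbouring genes shifted together on some chromosomes. For windows and chromosomes, log2 changes were taken relative to the median of all genes, which was -0.071. Of 435 windows of 25 genes, 6 had a median beyond 0.3 on that scale, all lower. Of these, 5 were on chromosome 15 and 1 on chromosome 20 (2.6 to 5.1 Mb). The highest count in 1000 shuffles of gene order was 1, and 5 windows were kept after GC content and gene length trends were removed. None was beyond 0.3 when an OS5K library was set against the other OS5K libraries. On chromosome 15, 87.0% of 384 tested genes lay below the median of all genes, with a chromosome median of -0.266 relative to it. Of the 375 genes called lower by limma, 42 lay on this chromosome, and of the 356 called higher, 9. A lower dosage of chromosome 15 in OS5K cells is a candidate explanation, as a hypothesis formed on these data, since RNA levels alone do not measure DNA copies. Other chromosome medians also lay outside 1000 random gene sets of the same size: chromosomes 20 (-0.209, 81.9% of 331 genes below) and 11 (-0.113, 72.4% below, from -0.195 to -0.056 over the OS5K libraries) on the lower side, and chromosomes 3 (0.051), 8 (0.094), 19 (0.069, but 0.007 in OS5K 3) and 22 (0.068, but -0.022 in OS5K 1) on the higher side. No dosage explanation was tested for these. Every window median lay below that of all genes on chromosome 15 (15 of 15), but also on chromosomes 20 (13 of 13) and 11 (26 of 26). A shift along the whole chromosome is thus not particular to chromosome 15.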
